A study of Arabidopsis thaliana with 3 samples.

How the data were processed

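Gene expression was measured by sequencing of polyadenylated RNA from 3 samples of wild-type Arabidopsis thaliana (Col-0). Per the labels' protocols, plants were kept at 21 °C in long days (16 h of light, 8 h of dark) on agar (0.8%) medium that contained sucrose (1.5%), RNA was taken from seedlings aged 7 days, and first-strand cDNA was primed with random hexamers on fragmented mRNA. The deposited table holds whole-number counts per gene, with 1 column per library and 0 columns of other samples. The submitters' processing notes name HISAT2 2.1.0, featureCounts 1.6.1, DESeq2 and the TAIR10 genome, with no role or order. The gene annotation, the strand setting, the treatment of reads that fall on several genes and any filter are not given in the sources used here.

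Gene symbols, products, coordinates and merged exon lengths were taken from the RefSeq annotation of TAIR10.1, to which 37051 of 37336 gene identifiers (99.24%) matched; coordinates in the text are those of TAIR10.1, since the count table holds none. The 285 identifiers of organelle-encoded genes were left unmatched, and all had 0 counts in each library. By the same limit of 3 counts used below, that is at most 9.1e-06% of the counts in replicate 1. Since any filter is unknown, this limit covers counted reads only and does not give the organelle share of the RNA. The libraries held 32967215, 31761722 and 27069921 counts, so 3 counts, the limit that a count of 0 allows, stand for 0.0843, 0.0981 and 0.115 CPM in replicates 1, 2 and 3. Shares of counts carry exact binomial intervals, and summed counts carry exact Poisson intervals, at 95%. Intervals and limits cover counting error only. Where a gene shares exon positions with another gene on either strand, its count is uncertain.

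CPM were computed with TMM library sizes (edgeR 4.0.16, R 4.3.3), with factors of 1.079, 0.9631 and 0.9624. Scaling by total counts in place of TMM shifts all log2 values of replicate 1 by 0.11 relative to the mean of the 3. Levels compared between genes were CPM per kb of merged exons with a pseudocount of 0.1, and values compared between libraries were log2(CPM + 0.5). A gene was called detected at 1 CPM or more in each library. The 20 gene lists (201 genes), the 16 gene pairs, the tests of list level, list spread, gene pairs and variation, and the rule for naming genes were fixed before the data were examined. The lists cover the cohesin core, cohesin loading, PRC1, PRC1 recruitment and H2A deubiquitination, PRC2, histone H2A, embryo, flower, meristem, photosynthesis, root, stomatal and vascular genes, meiosis and pollen, the clock, heat, touch, pathogen and cold responses, and reference genes. Of the list members, 190 matched the reference by symbol or synonym, 9 had no symbol there and 2 had an alias. The rule named any member of lists of up to 12 genes, up to 6 highest and 3 lowest members of longer lists, the 10 genes with the highest mean CPM, and the 10 genes with the largest difference between libraries among those past the threshold with a mean of at least 10 CPM.

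With 1 group, no test between groups was possible. The level of a list was its median log2 level, placed among 10000 random lists of the same size from all matched genes. The spread of a list was the median SD over libraries, placed among 10000 random lists matched on mean expression in 20 bins. The difference of a list between a pair of libraries was the median log2 difference of its members with a mean of 1 CPM or more. It was placed among expression-matched random lists and was not among the tests fixed before the data were examined. Common dispersion and genes varying beyond the trend came from edgeR with an intercept-only design after filterByExpr (about 10 counts in each library), using its goodness-of-fit test on the trended dispersion with Benjamini-Hochberg adjustment at 0.05. Variation beyond counting error was a Poisson chi-square test on the same 19016 genes. Gene pairs were tested by a two-sided exact sign-flip permutation over the libraries. Product families of at least 10 tested genes were tested by Fisher's exact test, a step added after the data were seen. Trends on purine share, GC content, exon length and exon number were fitted by least squares over 16749 detected protein-coding genes, also after the data were seen. NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6 under Python 3.11.15 were used for these steps.

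The tests were run on simulated data. Counts were drawn for the 19016 genes at the measured means and dispersion, and 200 genes were raised in 1 library each. These 200 were taken from genes with higher mean counts. The goodness-of-fit test recovered 97 of them at a 4-fold change, 199 at 16-fold and 197 at 64-fold, with 3, 4 and 14 false calls. Recovery of lowered genes and of genes with few counts was not simulated. On 17050 simulated genes, 2 of 100 unchanged lists and 100 of 100 lists with their SD multiplied by 2 passed the upper limit of the list spread test, and removal of the trend left −1.91 of a lowering by 2 on the log2 scale. Genes varied independently in these simulations. They therefore do not give the rate of false calls for lists whose members move together in 1 library. Alternatives were DESeq2 1.42.0 size factors, total counts, other thresholds, filters, pseudocounts, expression bins and dispersions, CPM without length, and each library left out in turn. Alternatives based on a gene's mean over the libraries, and on removal of the composition trend, were added after the data were seen, since a minimum in each library leaves out genes that are low in a single library.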

Results

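Polyadenylated RNA was sequenced from 3 samples of whole wild-type Arabidopsis thaliana seedlings of the Col-0 accession at 7 days of age. All 3 samples formed 1 group, and no other genotype was analysed here. The series concerns how subunits of cohesin, the ring complex that holds chromosomes together, take part in directing monoubiquitination of histone H2A. These libraries therefore describe the wild-type state of that machinery, and no comparison between genotypes was made. The table held counts for 37336 genes, and the libraries totalled 32967215 counts for replicate 1, 31761722 for replicate 2 and 27069921 for replicate 3. At 1 CPM or more (counts scaled by TMM library size) in each of the 3 libraries, 17050 genes were detected. A further 12464 genes had 0 counts in every library. Nothing in the labels says that the replicates came from separate plants or cultures. The p-values of tests across libraries therefore measure the spread between these samples, which may be technical.

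Photosynthesis genes led the ranking by abundance. The 21 genes of this list took 14.5% ± 0.13 of all counts (SD, n = 3), and 20 of them were detected. CAB1 (AT1G29930, chromosome 1, 10477885 to 10479114), which encodes a chlorophyll-binding antenna protein of photosystem II, was the most abundant transcript in the table at 28730 ± 2640 CPM (SD, n = 3). RBCS1A (AT1G67090, chromosome 1, 25048158 to 25049667), a small subunit of the carbon-fixing enzyme Rubisco, followed at 13500 ± 449 CPM. RCA (AT2G39730), the Rubisco activase, reached 11980 ± 1489 CPM, CAB2 (AT1G29920) 10920 ± 43.2 CPM and CAB3 (AT1G29910) 7903 ± 560 CPM. The remaining 5 of the 10 most abundant genes were LHCA4 (AT3G47470) at 7808 ± 410 CPM, LHCB5 (AT4G10340) at 6710 ± 1668 CPM, RBCS3B (AT5G38410) at 6673 ± 2071 CPM, LHCA1 (AT3G54890) at 6377 ± 849 CPM and LHCB3 (AT5G54270) at 5883 ± 756 CPM. Together these 10 genes held 10.7% ± 0.337 of the counts, and the 100 most abundant genes held 30.2% ± 1.58 (SD, n = 3). By CPM per kb of merged exons, the lowest members of the list were LHCB1.5 (AT2G34420), listed at 0 in all 3 libraries, RBCS1B (AT5G38430) at 815 ± 46.7 CPM and LHCB1.4 (AT2G34430) at 2631 ± 197 CPM. The exons of LHCB1.5 were covered by another annotated gene over 100% of their length. Several CAB, LHCB1 and RBCS genes are close copies of one another, so how reads were divided between them is uncertain.

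Of the 7 listed genes of the cohesin ring 6 were detected. Their median level lay at percentile 70.9 of random lists from all genes but at 0.98 when only detected genes formed list and background. SCC3 (AT2G47980, chromosome 2, 19631207 to 19636978), the subunit that binds the kleisin, stood at 48.3 ± 4.51 CPM (SD, n = 3). Among the 4 kleisin genes, which close the ring, SYN4 (AT5G16270, chromosome 5, 5316197 to 5322700) was at 43.2 ± 5.41 CPM, SYN2 (AT5G40840) at 2.69 ± 0.793 CPM and SYN3 (AT3G59550) at 2.63 ± 0.195 CPM. The meiotic kleisin SYN1 (AT5G05490) had 11, 6 and 1 counts in replicates 1, 2 and 3 and was not detected. Per kb of merged exons, SYN4 exceeded SYN3 10.05-fold (log2 ratio 3.33 ± 0.08, SD, n = 3) and SYN2 12.9-fold (3.69 ± 0.21), in 3 of 3 libraries each. These log2 ratios were 3.983 and 3.985 without the length correction and 2.597 and 2.781 with a pseudocount of 1. The ring's ATPases differed more between libraries. SMC1 (AT3G54670, chromosome 3, 20235506 to 20244046) was at 37.8, 6.70 and 3.84 CPM in replicates 1, 2 and 3, and SMC3 (AT2G27170, chromosome 2, 11609073 to 11617496) at 29.1, 8.04 and 4.65 CPM. Both varied beyond genes of like abundance (edgeR goodness-of-fit test with Benjamini-Hochberg adjustment, adjusted p = 7.27e-05 for SMC1 and 0.0128 for SMC3). The other 4 tested members did not pass, and the count of 2 was the same adjusted over the list alone. The log2 ratio of SMC1 to SMC3 per kb was 0.473, −0.151 and −0.155 in replicates 1, 2 and 3. Its mean of 0.06 ± 0.36 (SD, n = 3) turned to −0.05 without the length correction and −0.15 without replicate 1.

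Of 11 genes for cohesin loading, release and establishment, 10 were detected. The loader SCC2 (AT5G15540) was at 19.6 ± 9.15 CPM and its partner SCC4 (AT5G51340) at 21.7 ± 2.27 CPM (SD, n = 3). The release factors WAPL1 (AT1G11060) and WAPL2 (AT1G61030) were the steadiest of the group, at 16.0 ± 0.445 and 12.4 ± 0.816 CPM. The PDS5 genes, whose products regulate cohesin on chromatin, ranged from PDS5D (AT1G80810) at 14.34, 3.20 and 1.84 CPM in replicates 1, 2 and 3 to PDS5A (AT5G47690) at 127.9, 54.5 and 39.96 CPM. PDS5E (AT1G15940, chromosome 1, 5473359 to 5478405) was at 43.6, 3.20 and 2.61 CPM in replicates 1, 2 and 3, beyond the spread of genes of like abundance (edgeR goodness-of-fit test with Benjamini-Hochberg adjustment, adjusted p = 6.57e-09). PDS5C (AT4G31880; adjusted p = 0.0325) and PDS5D (adjusted p = 0.0221) passed the same edgeR test over all genes. With PDS5A, which passed only adjusted over the list alone, 4 genes passed over the list and 3 over all genes tested. PDS5B (AT1G77600) was at 11.7 ± 6.16 CPM, and the separase gene ESP (AT4G22970) at 4.57 ± 1.93 CPM. The acetyltransferase gene CTF7 (AT4G31400) was at 0.941 ± 0.123 CPM and shared 43.2% of its exon length with another gene, so its value is uncertain.

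The RING-finger genes that monoubiquitinate H2A stood below SCC3 and SYN4. In the list of Polycomb repressive complex 1 (PRC1), 6 of 7 genes were detected. The RING-finger genes BMI1A (AT2G30580, chromosome 2, 13025911 to 13030661) and BMI1B (AT1G06770, chromosome 1, 2078880 to 2082097) stood at 8.73 ± 2.53 and 8.46 ± 1.99 CPM (SD, n = 3), and BMI1C (AT3G23060) at 0.180 ± 0.121 CPM. Per kb, BMI1A exceeded BMI1C 19.6-fold in 3 of 3 libraries, although BMI1C had only 6, 2 and 8 counts, and the log2 ratio of 4.29 ± 0.545 (SD, n = 3) became 5.035 without the length correction and 2.068 with a pseudocount of 1. RING1A (AT5G44280) was at 6.33, 2.94 and 1.96 CPM and RING1B (AT1G03770) at 5.68, 1.80 and 1.65 CPM in replicates 1, 2 and 3. The associated genes EMF1 (AT5G11530) and LHP1 (AT5G17690), whose product binds trimethylated H3K27, were higher, at 19.7 ± 7.96 and 20.3 ± 2.87 CPM. None of the 6 tested PRC1 genes varied beyond genes of like abundance by edgeR's goodness-of-fit test, with 0 at an unadjusted p under 0.05. DESeq2 marked 0 of the 6 as dispersion outliers, which decides little, since it marked only 23 of 19016 genes. All 6 nevertheless had their highest value in replicate 1, with a median log2 difference of 0.80 from replicate 2 and 0.77 from replicate 3, against 0.08 between replicates 2 and 3.

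**Figure D1:**
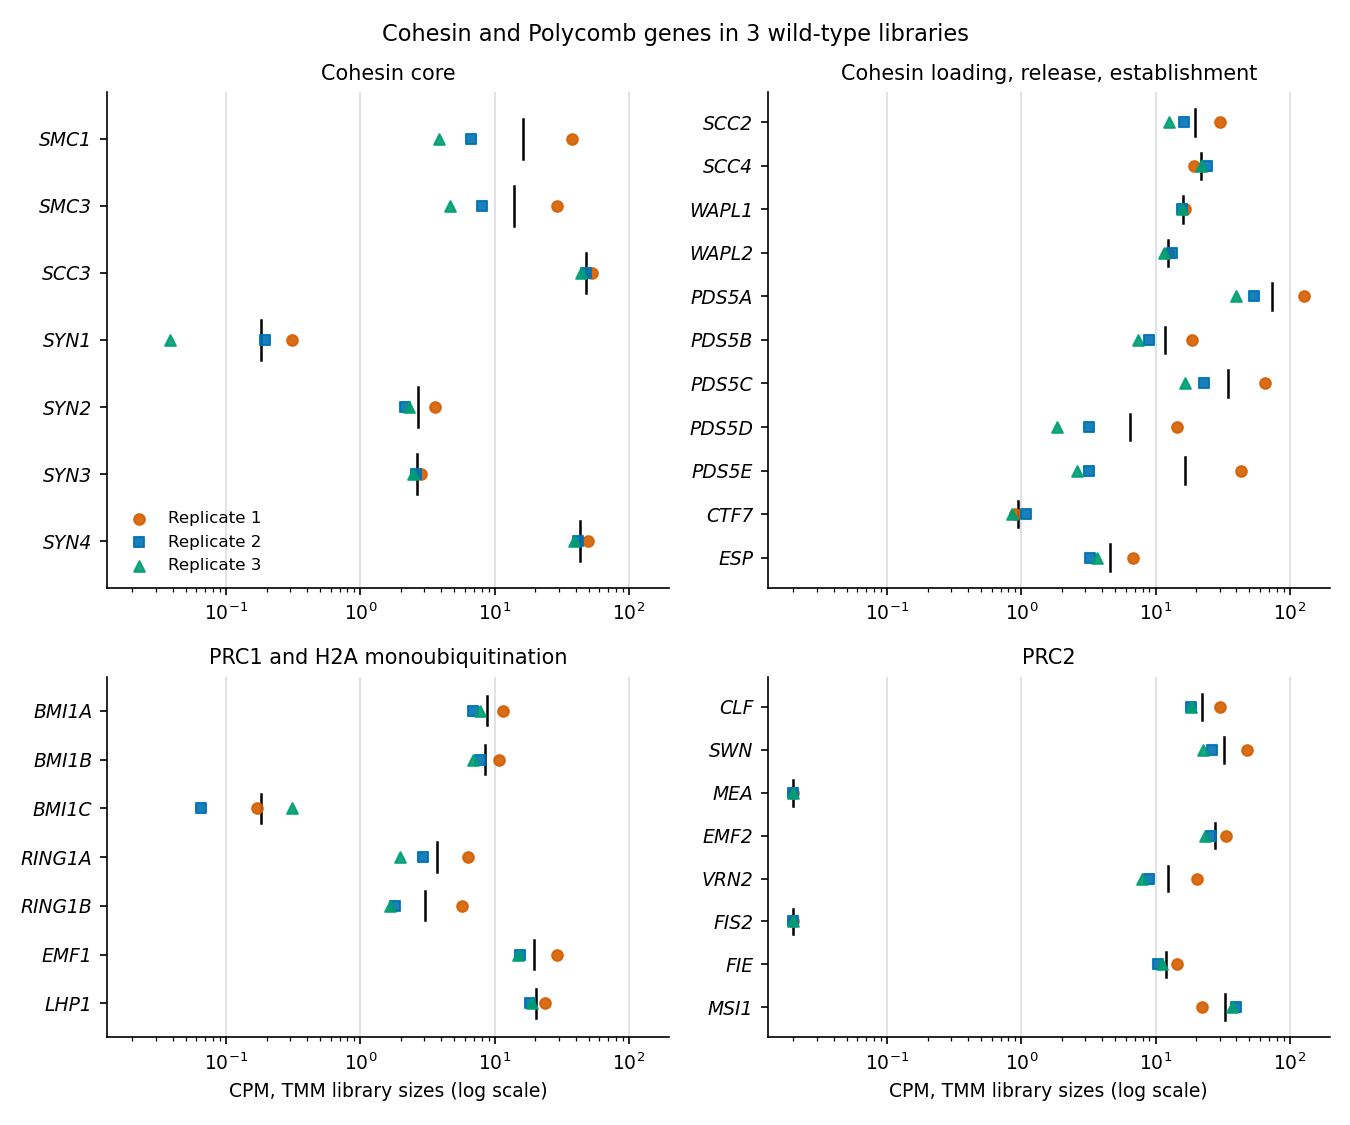
CPM (log scale) of the cohesin core, cohesin regulators, PRC1 and PRC2 genes, with 1 symbol per wild-type library and a black tick at the mean of the 3 libraries; genes with 0 counts (MEA and FIS2) are drawn at the left edge. SMC1, SMC3 and PDS5E lie apart in replicate 1, at 37.8, 29.1 and 43.6 CPM, while SCC3 and SYN4 lie together near 48.3 and 43.2 CPM.

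Genes that bring PRC1 to chromatin or reverse its mark were all detected. The median level of the 12 lay at percentile 99.8 of 10000 random lists of 12 genes, but at 86.9 when only detected genes formed list and background. The B3-domain repressors VAL1 (AT2G30470) and VAL2 (AT4G32010) were at 38.4 ± 8.25 and 31.1 ± 3.53 CPM (SD, n = 3), and VAL3 (AT4G21550) at 1.64 ± 0.508 CPM. Per kb, VAL1 exceeded VAL3 15.9-fold in 3 of 3 libraries, and the log2 ratio of 3.99 ± 0.193 (SD, n = 3) became 4.49 without the length correction and 2.91 with a pseudocount of 1. The Alfin-like readers of methylated H3K4 ranged from AL5 (AT5G20510) at 5.97 ± 2.73 CPM to AL4 (AT5G26210) at 78.8 ± 17.6 CPM. The deubiquitinase genes UBP12 (AT5G06600) and UBP13 (AT3G11910) were at 64.4 ± 10.7 and 57.1 ± 7.61 CPM. The 12 listed H2A genes, which encode the substrate, were all detected and lay at percentile 100 of random lists. They were led by the H2A.Z gene HTA9 (AT1G52740) at 155 ± 17.1 CPM and HTA10 (AT1G51060) at 99.6 ± 24.5 CPM. HTA8 (AT2G38810) stood at 11.03 ± 0.359 CPM. HTA3 (AT1G54690) and HTA12 (AT5G02560) shared 62.3% and 34.7% of their exon length with other genes, so their values are uncertain.

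Of 8 PRC2 genes, which trimethylate H3K27, 6 were detected. SWN (AT4G02020) was at 32.2 ± 13.6 CPM, CLF (AT2G23380) at 22.3 ± 6.68 CPM, EMF2 (AT5G51230) at 27.5 ± 5.41 CPM and VRN2 (AT4G16845) at 12.4 ± 6.83 CPM (SD, n = 3). MSI1 (AT5G58230) was at 32.99 ± 9.49 CPM and FIE (AT3G20740) at 11.99 ± 2.13 CPM. The endosperm members MEA (AT1G02580) and FIS2 (AT2G35670) had 0 counts in each library. CLF was at least 109.5-fold above MEA and EMF2 at least 195.5-fold above FIS2 per kb, taking 3 counts per library as the limit a count of 0 allows. Across 16 pairs of related or partner genes, 14 held the same direction in 3 of 3 libraries. With 3 libraries a two-sided exact sign-flip permutation test cannot go below p = 0.25, so no pair could pass, and the lowest Benjamini-Hochberg adjusted exact p was 0.286 (n = 3).

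Markers of other organs and conditions spanned a wide range of levels. Of 21 flower identity and flowering-time genes 9 were detected, led by the repressor SVP (AT2G22540) at 65.4 ± 8.78 CPM, FLM (AT1G77080) at 26.1 ± 5.70 CPM, SOC1 (AT2G45660) at 21.7 ± 6.03 CPM, MAF3 (AT5G65060) at 10.3 ± 4.19 CPM and SEP3 (AT1G24260) at 2.34 ± 0.810 CPM (SD, n = 3). MAF2 (AT5G65050) was at 44.6, 14.15 and 12.44 CPM in replicates 1, 2 and 3. STK (AT4G09960) had 0 counts, AP1 (AT1G69120) had 2, 3 and 0 counts and SHP2 (AT2G42830), which shared 56.7% of its exon length with another gene, was at 0.0405 ± 0.0354 CPM. Only 1 of 7 meiosis and pollen genes was detected, DMC1 (AT3G22880) at 4.26 ± 0.517 CPM, and VGD1, VGDH1 and HTR10 had 0 counts. Of 13 meristem genes 5 were detected, including SCR (AT3G54220) at 36.2 ± 2.31 CPM, KNAT1 (AT4G08150) at 14.7 ± 7.99 CPM and STM (AT1G62360) at 4.92 ± 1.53 CPM, while WUS (AT2G17950) and CLV3 (AT2G27250) stayed under 0.1 CPM on average. Of 9 stomatal and epidermal genes 7 were detected, with the epidermal regulators PDF2 (AT4G04890) at 89.98 ± 11.9 CPM and ATML1 (AT4G21750) at 87.3 ± 9.79 CPM, and the stomatal initiator SPCH (AT5G53210) at 4.44 ± 0.592 CPM. Of 6 vascular genes 5 were detected, led by the phloem sucrose transporter gene SUC2 (AT1G22710) at 212 ± 76.0 CPM. Of 12 clock genes 10 were detected, with LHY (AT1G01060) at 279 ± 56.9 CPM and CCA1 (AT2G46830) at 200 ± 102 CPM, TOC1 (AT5G61380) at 13.2 ± 1.51 CPM and PRR5 (AT5G24470) at 0.310 ± 0.0740 CPM. The sampling time of day is not given in the sources used here.

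Stress genes differed by class. All 6 cold, drought and abscisic acid genes were detected, in CPM not corrected for length from KIN1 (AT5G15960) at 24.1 ± 10.6 CPM to COR47 (AT1G20440) at 140 ± 27.7 CPM (SD, n = 3), and this list lay at percentile 99.6 of random lists, but at 94.8 among detected genes only. Of 4 pathogen-response genes only PR5 (AT1G75040) was detected, at 3.73 ± 1.97 CPM, and PR1 (AT2G14610) had 3, 0 and 0 counts in replicates 1, 2 and 3. Among 10 touch and wounding genes 9 were detected, led by TCH4 (AT5G57560) at 61.1 ± 6.48 CPM, and among 5 heat shock genes 4 were detected, including HSP101 (AT1G74310) at 44.2 ± 3.36 CPM and HSP90.1 (AT5G52640) at 42.5 ± 6.96 CPM. All 9 reference genes were detected, in CPM not corrected for length from TIP41 (AT4G34270) at 28.4 ± 2.28 CPM to UBQ10 (AT4G05320) at 1710 ± 389 CPM. All 9 were lower in replicate 1 than in each other library, with a median log2 difference of −0.493 from replicate 2 (percentile 4.3 of expression-matched random lists) and −0.555 from replicate 3 (3.935).

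Among the 20 lists, 5 lay in the highest 2.5% of random lists, namely photosynthesis, reference genes, histone H2A, PRC1 recruitment, and cold, drought and abscisic acid. In the lowest 2.5% lay 0 lists, which decides little, since 12464 of 37336 genes had 0 counts in every library. Random lists often tie at the bottom, so even a list wholly at 0 could hardly reach the lowest 2.5%. The percentile was 93.8 for PRC2, 90.6 for the clock, 86.8 for heat shock, 85.8 for stomatal genes, 84.7 for touch and 84.7 for vasculature. It was 80.6 for cohesin loading, 78.7 for PRC1, 70.9 for the cohesin core, 65.9 for root cell types and 47.8 for meristem genes. Embryo genes lay at 34.2, flower genes at 33.2, meiosis and pollen at 27.9 and pathogen response at 20.2. When only detected genes formed both lists and background, 3 lists stayed high, namely photosynthesis, reference genes and histone H2A, and the cohesin core was the 1 list in the lowest 2.5%.

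**Figure D2:**
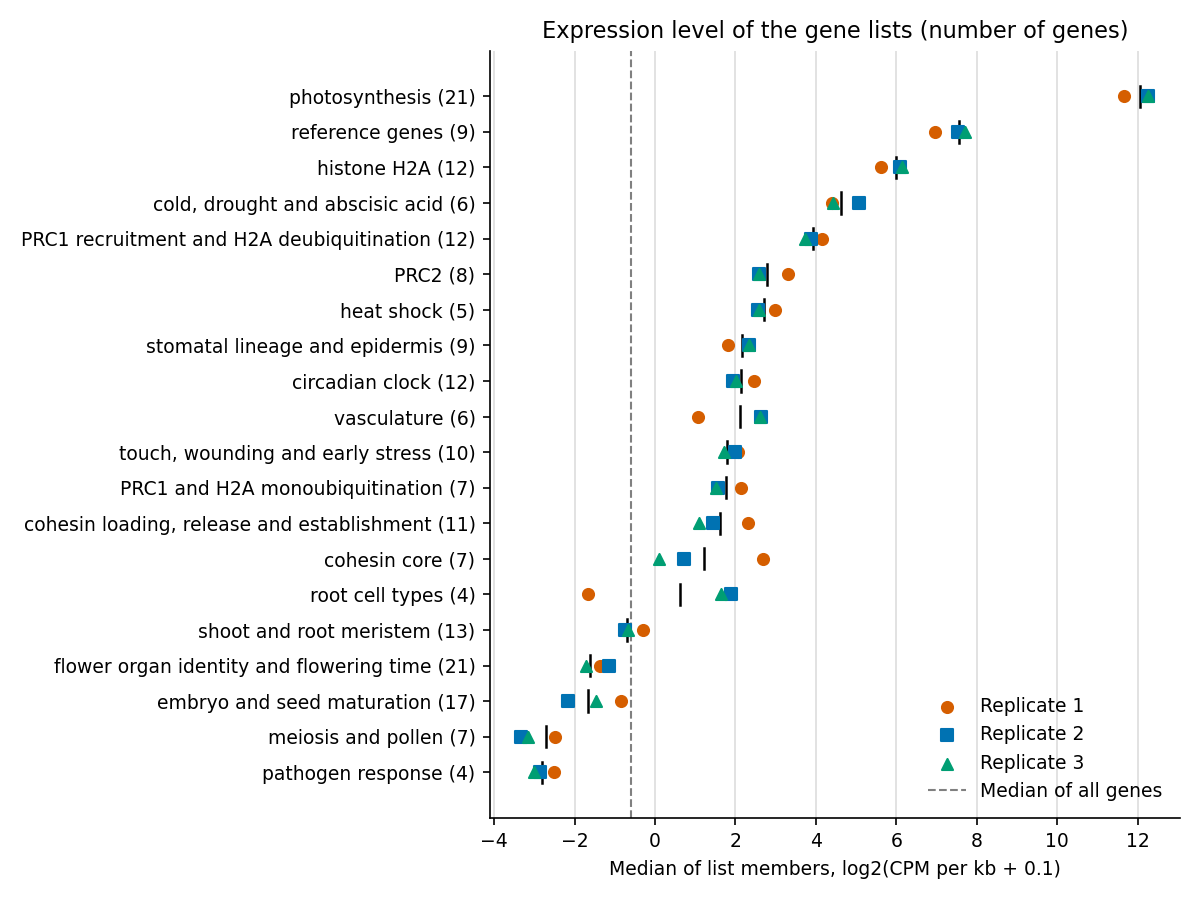
Median over each list's genes of log2(CPM per kb of merged exons + 0.1), with 1 symbol per wild-type library, a black tick for the value over the 3 libraries and a dashed line at the median of all genes (−0.60). Photosynthesis lies highest at 12.06, and root cell types show the widest gap between libraries, from −1.66 to 1.90.

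The 3 wild-type libraries were not equally close. Across 17050 detected genes, Pearson's r of log2(CPM + 0.5) was 0.993 between replicates 2 and 3, 0.934 between 1 and 2 and 0.920 between 1 and 3; these are correlations across genes, which are not independent replicates. The number of genes that differed by more than 2-fold was 33, 1909 and 2377 for the same pairs. In every pair, counts differed by more than counting error, with a chi-square per degree of freedom of 10.2, 84.0 and 95.4. No pair was therefore a single set of counts deposited again. Whether 1 library was sequenced or aligned more than once was not tested. The biological coefficient of variation over all 3 was 0.319 (edgeR common dispersion). It was 0.0949 without replicate 1, 0.397 without replicate 2 and 0.366 without replicate 3.

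Replicate 1 stood apart in nearly all genes that varied beyond the trend. By edgeR's goodness-of-fit test with Benjamini-Hochberg adjustment, 386 of 19016 genes varied beyond genes of like abundance. Replicate 1 was the library farthest from the others in 381 of them, lowest for 204 and highest for 177. The proline-rich extensin-like genes AT1G23720 (chromosome 1, 8388297 to 8391623; adjusted p = 2.38e-14) and AT3G28550 (chromosome 3, 10700562 to 10704018; adjusted p = 2.38e-14) were at 1.52, 73.7 and 80.5 CPM and at 1.63, 79.4 and 78.8 CPM in replicates 1, 2 and 3. The glycine-rich gene AT1G04800 was at 1.74, 62.7 and 58.0 CPM, the lectin gene AT1G52070 at 0.450, 25.4 and 16.6 CPM, and the extensin-like gene AT3G54580 at 1.52, 47.7 and 50.2 CPM. HRGP1 (AT3G54590), the peroxidase gene AT5G17820, the lipid-transfer gene AT4G22517 and the vacuolar channel gene TIP2;3 (AT5G47450) were lowest in replicate 1 as well, at 0.506, 1.66, 2.25 and 1.32 CPM. LINC2 (AT1G13220, chromosome 1, 4515464 to 4520306), which encodes a coiled-coil protein of the nuclear lamina, went the other way, at 30.5, 2.39 and 1.08 CPM (adjusted p = 1.88e-08, edgeR). Extensin-like genes are repetitive and similar to one another, so how their reads were divided is uncertain. Without replicate 1 the test called 61 genes, 7 of them among the 386, and none of these 10 genes; it called 123 without replicate 2 and 128 without replicate 3, where fewer samples also lower its power. DESeq2 marked 23 genes as dispersion outliers, including all 10. Beyond counting error alone 14906 genes varied (chi-square test, Benjamini-Hochberg), and 4788 did so without replicate 1.

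**Figure D3:**
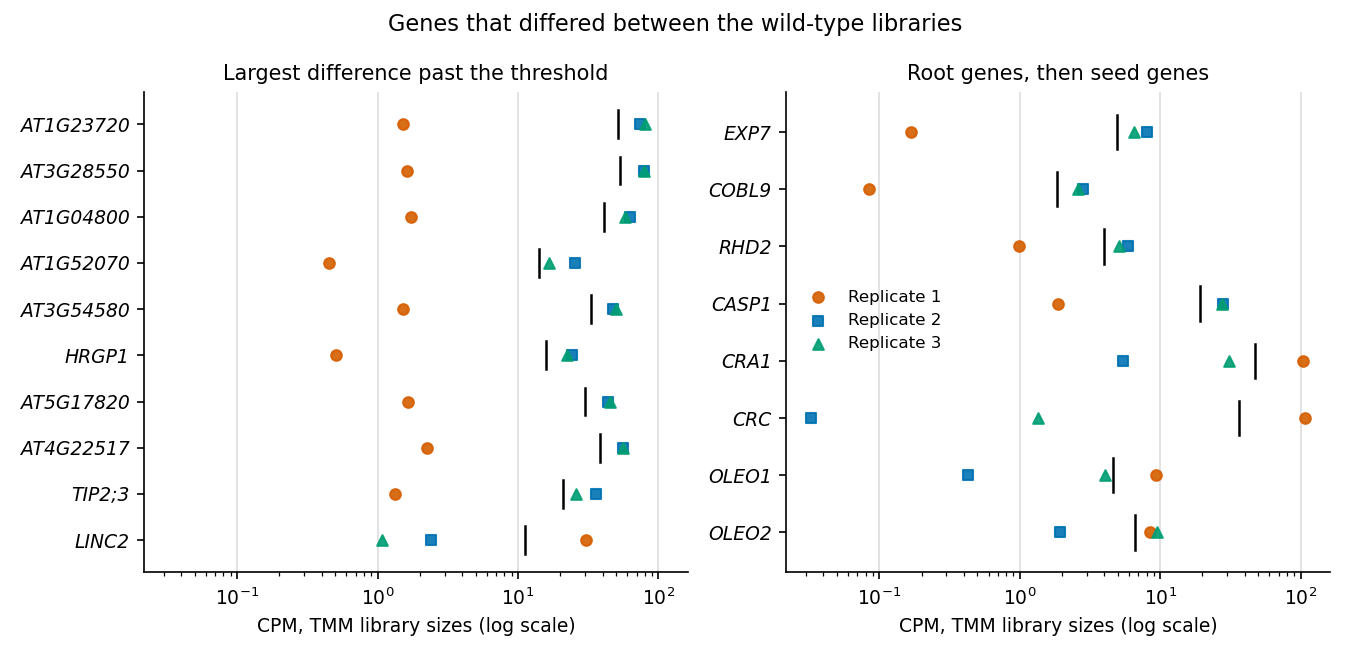
CPM (log scale) of the 10 genes with the largest difference between libraries among those past the edgeR threshold (left), and of root and seed genes (right), with 1 symbol per wild-type library and a black tick at the mean. For 9 of the 10 genes on the left, replicate 1 lies lowest, as for AT1G23720 at 1.52 CPM against 73.7 and 80.5 CPM.

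Gene families defined by their annotated product were unevenly represented among the 386 genes. Of 175 families tested, 11 were over-represented (one-sided Fisher's exact test with Benjamini-Hochberg adjustment against the 19016 tested genes). This test takes genes as independent, although members of a family may vary together. Replicate 1 was farthest from the others in 381 of the 386 genes. The family p-values therefore describe these gene lists and do not measure spread between samples. Class III peroxidases, which act on cell wall polymers, contributed 17 of 43 members (adjusted exact p = 5.41e-16), and the lipid-transfer and seed albumin superfamily 15 of 44 (3.68e-13); replicate 1 was lowest in all of them. Mannose-binding lectins followed with 4 of 13 members (3 lowest and 1 highest in replicate 1), then glycine-rich proteins with 5 of 25, dirigent-like proteins with 4 of 15, and Pollen Ole e 1 and extensin proteins with 4 of 15, each at an adjusted exact p of 0.00557. The Tudor/PWWP/MBT superfamily was the 1 over-represented family whose called members, 3 of 12, were all highest in replicate 1 (adjusted exact p = 0.0333). These were PDS5D, PDS5E and, named after its values were seen, AT5G40340 at 67.8, 5.002 and 3.69 CPM. GDSL lipases (5 of 43), HXXXD acyl-transferases (5 of 43), a family of pectin methylesterase inhibitors (3 of 14) and UPF0497 proteins (4 of 30) completed the set. Another product label for pectin methylesterase inhibitors, with 2 of 18 members called, did not pass (Fisher's exact test, adjusted p = 0.555).

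Markers of root cell types were lower in replicate 1. Counts of the 4 root genes, namely the root hair genes EXP7 (AT1G12560), COBL9 (AT5G49270) and RHD2 (AT5G51060) and the endodermal gene CASP1 (AT2G36100, chromosome 2, 15159591 to 15160799), summed to 3.12 CPM in replicate 1 (95% exact Poisson interval 2.57 to 3.76), 44.8 in replicate 2 (42.5 to 47.3) and 41.9 in replicate 3 (39.4 to 44.4). CASP1 passed edgeR's goodness-of-fit test with Benjamini-Hochberg adjustment (adjusted p = 7.63e-06), and RHD2 did so adjusted over the list alone (adjusted p = 0.0113), for 1 and 2 genes of the 2 tested. Secondary wall cellulose synthase genes of the vasculature were also lowest in replicate 1. CESA7 (AT5G17420) was at 5.17, 18.21 and 18.77 CPM and CESA8 (AT4G18780) at 2.22, 13.0 and 11.4 CPM. Of the vasculature list, 0 of 5 tested genes passed over all genes by edgeR's test, 2 passed adjusted over the list alone and 3 had an unadjusted p under 0.05. DESeq2 marked 0 of them as outliers, but only 23 genes over all lists and other genes.

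Some seed storage and oil body genes differed between the libraries. CRC (AT4G28520), a cruciferin, was at 107.5 CPM in replicate 1, from 3825 counts, and had 1 and 35 counts in replicates 2 and 3, too few for the filter of the edgeR test. The cruciferin gene CRA1 (AT5G44120, chromosome 5, 17756238 to 17758336) was at 104.5, 5.46 and 30.9 CPM (edgeR goodness-of-fit test with Benjamini-Hochberg adjustment, adjusted p = 4.7e-09). The oleosin gene OLEO1 (AT4G25140) was at 9.39, 0.425 and 4.07 CPM (adjusted p = 0.00287, same edgeR test) and OLEO2 (AT5G40420), which did not pass over all genes (adjusted p = 0.291), at 8.52, 1.93 and 9.52 CPM. Of 7 embryo and seed genes tested, 2 passed over all genes and 3 adjusted over the list alone. OLEO4 (AT3G27660) and AGL15 (AT5G13790) were steady at 3.05 ± 0.424 and 2.67 ± 0.594 CPM (SD, n = 3). LEC1 and CRB had 0 counts, and SESA3 (AT4G27160) had 1, 0 and 0 counts. ADH1 (AT1G77120), an alcohol dehydrogenase of hypoxia and abscisic acid responses, was the 1 gene of the cold list past the edgeR threshold, at 21.5, 112 and 143 CPM (adjusted p = 0.000143).

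In 15 of the 20 lists no gene passed edgeR's goodness-of-fit test over all genes. Of their 126 tested genes, 9 had an unadjusted p under 0.05, 5 passed adjusted over the list alone (MAF2, GAPC1, KAT1, CESA7 and CESA8), and 0 were DESeq2 outliers. With only 23 outliers among 19016 genes, that 0 decides little. Set against expression-matched random lists, 4 of 17 lists had a spread between libraries in the highest 2.5% and 1 in the lowest 2.5%. The median SD of log2(CPM + 0.5) was 0.65 for cohesin loading (percentile 99.97), 0.58 for the cold list (99.85), 0.71 for embryo genes (99.06) and 0.78 for vasculature (99.79). Photosynthesis genes varied least, at 0.13 (percentile 1.93). PRC1 lay at percentile 90.95, PRC2 at 94.4, the clock at 94.47, reference genes at 87.81, stomatal genes at 72.74 and flower genes at 71.03. PRC1 recruitment lay at 48.9, the cohesin core at 44.52, heat shock at 43.3, touch at 33.28, histone H2A at 29.11 and meristem genes at 27.4. Root cell types, meiosis and pathogen response had fewer than 3 detected members. When members and background needed only a mean of 1 CPM, a rule added after the data were seen, 5 lists lay in the highest 2.5%, since root cell types then had 4 members with a median SD of 1.735 (percentile 100), and the median SD of the embryo list was 1.441. Without replicate 1, the 4 root genes were all detected and lay at 46.12. Cohesin loading then lay at 95.96 and vasculature at 27.7; the embryo list lay at 72.27 without replicate 2 and at 97.47 without replicate 3, and the cold list at 95.71 without replicate 3. Photosynthesis lay at 4.07 without replicate 2 and 13.81 without replicate 3. Without replicate 3, PRC2 lay at 97.82, the clock at 98.13 and touch at 2.18, past the limits they did not reach with all 3 libraries.

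Differences between libraries also followed the base composition of the gene. The purine share is the percentage of A and G in a gene's merged exons on the sense strand. In the most purine-rich eighth of detected protein-coding genes, the median log2 difference was 0.53 for replicate 1 minus 2, 0.68 for 1 minus 3 and 0.15 for 2 minus 3, and in the least purine-rich eighth it was −0.25, −0.34 and −0.10. SMC1, PDS5E and PDS5C, all highest in replicate 1, had purine shares of 58.6%, 58.5% and 56.3%, and WAPL1, which was steady, had 50.6%. Single genes departed from the trend, whose r squared was 0.1463 for replicate 1 minus 2. SCC3 and SYN4, at 54.2% and 54.4%, lay in the most purine-rich eighth but differed by only 0.14 and 0.24 for replicate 1 minus 2, and HSP90.1, at 59.0%, was lower in replicate 1 by 0.47. After the trend on purine share, GC content, exon length and exon number was subtracted, the median difference of the cohesin loading list was 0.30 for replicate 1 minus 2 (percentile 91.55), from 1.001 before, 0.51 for 1 minus 3 (98.98), from 1.244, and 0.148 for 2 minus 3 (98.41), from 0.244, so 2 of the 3 pairs stayed in the highest 2.5% of random lists. For the PRC1 list it was 0.32 (percentile 81.01), from 0.80, and 0.44 (89.87), from 0.77, for replicate 1 minus 2 and 1 minus 3. For the reference genes it was −0.224 (percentile 23.25), from −0.493, and −0.292 (10.75), from −0.555, in the same order. Not every list shrank. For replicate 1 minus 2, the clock list stayed at 0.478 (percentile 99.52), from 0.555 (99.89), the cold list went to −0.892 (0.03) from −0.342 (8.57), and photosynthesis to 0.212 (99.91) from −0.214 (69.51). The spread of the cohesin loading list then lay at percentile 85.96 and that of photosynthesis at 76.82.

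**Figure D4:**
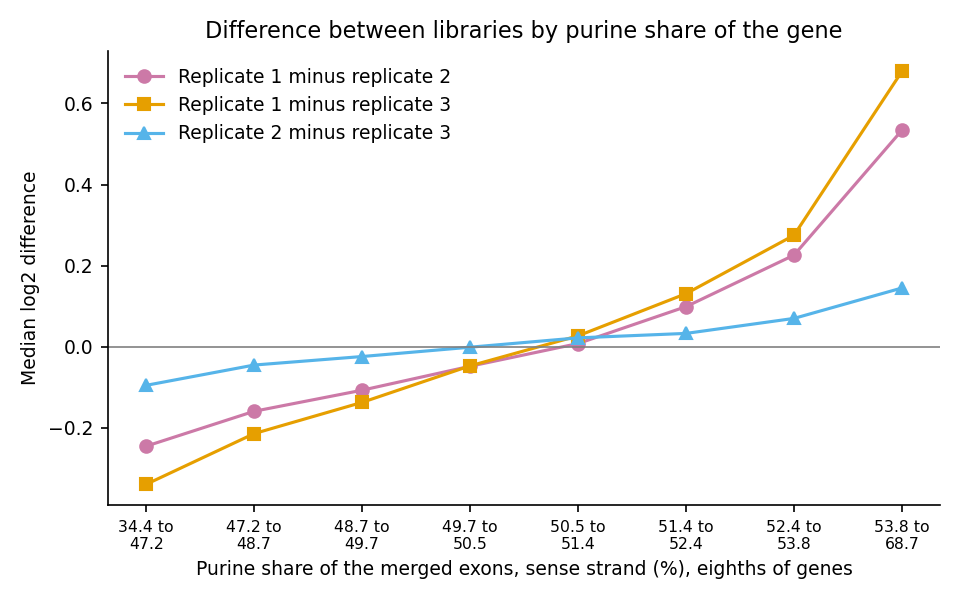
Median log2 difference in CPM for each pair of wild-type libraries (vertical axis) over 8 equal groups of detected protein-coding genes ordered by purine share in percent (horizontal axis). Replicate 1 minus replicate 3 runs from −0.34 to 0.68, replicate 1 minus replicate 2 from −0.25 to 0.53 and replicate 2 minus replicate 3 from −0.10 to 0.15.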

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

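The alternatives based on mean CPM, on mean counts and on removal of the composition trend were chosen after the data were seen. Genes detected stayed between 12864 (5 CPM) and 18325 (0.5 CPM), the photosynthesis share between 14.41% and 14.54%, the lists past either limit of level at 4 or 5 (3 high and 1 low among detected genes only), and the pairs with 1 direction at 12 to 15. With a library left out in turn, the coefficient of variation ran from 0.0949 to 0.397, genes beyond the trend from 61 to 128, genes beyond counting error from 4788 to 13893, and lists with a high spread from 2 to 4; these numbered 5 by mean CPM and 3 with the trend removed. The lowest value of each came without replicate 1. With fewer libraries the goodness-of-fit test has less power. All 10 named genes lost their call without replicate 1, with adjusted p from 0.333 to 1 (edgeR), and kept it under the other settings. Genes beyond the trend numbered 329 with total counts, of which 312 were shared with the 386, and 489 with a common dispersion. They numbered 436 without a filter on low counts (342 shared) and 460 with a mean of at least 10 counts (362 shared). DESeq2 dispersion outliers numbered 23; the cause was not tested. Without a length correction, 9 of 16 gene ratios moved by more than their SD, and with a pseudocount of 1, 6 did. SMC1 against SMC3, with a mean near 0, was the 1 ratio whose sign turned under any alternative. Depth limits genes such as BMI1C, with 6, 2 and 8 counts.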

Other observations

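In this section, the tests chosen after the result was seen were the interval for the root genes, the joint fit for purine share and the share of fully covered genes at 0.

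Genes of iron, phosphate and auxin transport in roots, listed as root genes once the low root markers had been seen but without their own values, were lowest in replicate 1. IRT1 (AT4G19690), the main iron transporter of the root epidermis, was at 1.43, 31.2 and 25.4 CPM in replicates 1, 2 and 3. The phosphate transporter gene PHT1;1 (AT5G43350) was at 5.43, 54.4 and 60.5 CPM, the auxin efflux carrier EIR1 (AT5G57090) at 2.42, 20.4 and 19.5 CPM, and the root hair gene PRP3 (AT3G62680) at 0.141, 9.02 and 8.83 CPM.

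Root genes were lower in replicate 1 than in replicates 2 and 3. Over the 11 of 18 further root genes with a mean of 1 CPM or more, 11 were lower in replicate 1 than in each other library, with a median log2 difference of −2.90 from replicate 2 and −2.86 from replicate 3, against 0.04 between replicates 2 and 3. Base composition and length did not account for it, since the 4 fixed root genes still had a median of −2.70 after the trend was subtracted, and neither did counting error, with an upper limit of 3.76 CPM in replicate 1 against a lower limit of 42.5 in replicate 2. A candidate explanation is that replicate 1 held less root tissue, which the median of −2.90 fits. Photosynthesis genes did not decide it. Their median difference was −0.214 from replicate 2 and −0.197 from replicate 3, at percentiles 69.51 and 81.22 of expression-matched random lists. It was 0.212 and 0.363 after the trend was subtracted, so its sign depended on the correction. The correction also raised the photosynthesis median for replicate 2 minus 3 to 0.184 from 0.005, although the further root genes differed there by only 0.04. The photosynthesis share of counts was 14.58%, 14.5% and 14.32% in replicates 1, 2 and 3. No biological explanation beyond tissue content was tested because the labels give 1 group. Among root meristem genes named after their values were seen, PLT1 (0.590, 1.144 and 0.921 CPM) and PLT2 (0.366, 0.523 and 1.152 CPM) were lowest in replicate 1, WOX5 was highest there (0.534, 0.425 and 0.422 CPM) and SCR only slightly lower (33.7, 38.1 and 36.9 CPM); all but SCR had at most 35 counts in a library and decide little.

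Purine-rich genes, among them SMC1, SMC3 and PDS5E, were higher in replicate 1. Less root tissue did not account for this, since the slope for replicate 1 minus 2 was 0.118 log2 per percent of purine within 131 genes with chloroplast, photosystem or chlorophyll products, against 0.085 over all 16749 genes. Gene length, GC content and exon number did not either, since the slope was 0.0783 with these in the fit. The slope on purine share lay above 0, interval included, in 8 of 8 of the largest product families, which fits a sequence-dependent bias of the libraries. The data do not separate a bias in library preparation from one in sequencing or alignment. No biological origin other than root content was tested. The high values of cohesin genes in replicate 1 may come partly from such a bias. SMC1, SMC3 and PDS5E differed by 2.412, 1.794 and 3.572 for replicate 1 minus 2, against a median of 0.534 in the most purine-rich eighth. Their differences thus went well beyond that median.

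Protein-coding genes that lie under other genes were often listed at 0. Of 368 genes whose exons were fully covered by other genes, 99.18% had 0 counts in all 3 libraries, against 18.19% of 19818 uncovered genes. Of the fully covered genes, 167 were in a named product family, and 98.2% of these were at 0. Silence in seedlings did not account for these, since 17.11% of 2630 uncovered genes of the same families were at 0. For the remaining fully covered genes, silence was not tested by family. A candidate explanation is that reads falling on more than 1 gene were left uncounted, so that a 0 for a gene such as LHCB1.5 may not show absence of its transcript.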
